A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

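The series held 27 libraries of Saccharomyces cerevisiae: 19 of RNA and 8 of ChIP DNA. Per the labels, cells for RNA grew in YPD to an OD600 of 0.8 to 1 and libraries were made with a TruSeq v2 kit; the cells for Arp5 ChIP were arrested with nocodazole, released into alpha-factor and taken at an OD of 0.6, and their chromatin was cut with micrococcal nuclease. The ChIP libraries of arp5 carry the genotype WT in a label field; the titles were used, and the ARP5 gene was checked, where the authors' deposited table of arp5 over BY4741 H3K79me3 stands at -8.42 (log2).

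The authors' deposited RNA values are FPKM, made with TopHat2 2.0.8, Bowtie and Cuffdiff 2.0.2 on sacCer3 according to the submitters' processing notes, with 8 columns for 8 genotypes and 6664 genes. Duplicates were pooled before deposit, and which libraries entered the pooled columns is not given in the sources used here. The authors' deposited ChIP values are log2 ratios of the precipitate over its input in windows of 50 bp, aligned with Bowtie 0.12.9 per the submitters' processing notes, with lists of significant windows for Arp5 and for both marks in BY4741. The scaling, the caller and its threshold are not given in the sources used here. The authors' deposited table of arp5 over BY4741 H3K79me3 holds log2 ratios of the same windows. The authors' deposited metagene tables, 13 of them and 8 by strand, hold log2 ratios of mutant over wild type in 35 windows per gene: 10 of 100 bp before it, 15 equal parts of it and 10 of 100 bp after it. The TruSeq v2 kit does not keep the strand of the RNA, and how reads of each strand were told apart is not given in the sources used here, so what the sense and antisense values measure is uncertain. No read totals come with any of these values, so depth is unknown and no interval from counts is given.

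Before the data were examined, limma tests across duplicates had been planned, together with a fallback for a table of 1 column per genotype; the gene lists, the rule for named genes, the 20 kb zone and most alternatives were fixed at that time too. The table had 1 column per genotype, so the fallback was used and no test was run. Each gene was given log2 of (FPKM + 1) in the mutant over the same in its wild type, CY337 for ino80 and BY4741 for the others, and the double mutant was also set against sir3 and arp5. A gene counted when it had at least 5 FPKM in either genotype, and as changed past 2-fold, with the deleted genes left out. Values of exactly 0 are called listed at 0 and have no fold. Lists and zones were summarised by the median over members with a mean FPKM of at least 1, set against 10000 random lists of the same size drawn within 20 classes of expression; the central 95% of these is a description and not a test. Of 27 lists 26 had members in the table; the list of mitochondrial genome genes had 0 of 8 and was left out, and amino acid synthesis had 36 of 37. Positions are those in the authors' files, and symbols come from a reference table that matched 5989 genes; the distance from an end is the authors' own.

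Named genes are the deleted genes; the 8 largest rises and falls of each comparison past 2-fold, without the deleted gene, its neighbours and genes listed at 0; up to 2 highest and 2 lowest members of each list; the 6 largest rises and falls within 20 kb of an end; and HMLALPHA1, HMLALPHA2, HMRA1, HMRA2, INO1, PHO5, PHO84, YFR057W, HIS3, LEU2, MET17 and URA3. Other named genes were chosen after their values were seen: genes by antisense RNA or Arp5 promoter, essential genes on III, MATALPHA1, and any list member outside its extremes. Chromosome medians used genes of at least 300 bp with at least 5 FPKM in both genotypes, relative to chromosomes other than I, III, XI and XII; this comparison was added after the values were seen. For ChIP, the median log2 was taken by distance from an end and for each of 32 ends, set against 1000 random sets of interior stretches beyond 50 kb; the excess is the arp5 minus BY4741 difference less its median over interior windows of the same BY4741 level, in 100 classes. Promoters were 500 bp before the gene. Similarity between mutants was set against 100 simulated draws in which the pairs share nothing but the control.

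Alternatives changed the pseudocount (0.1 or 5), the filter on low values (none, or a mean FPKM of 10), the scaling (centring, or quantile normalization), the zone (10 or 30 kb), promoter length (300 bp), the Arp5 list and the mean or median over genes. A count was called kept within 1.5 times its value and an Arp5 ratio within 1.1 times; another value was called kept inside the 95% interval of 500 draws with replacement of chromosomes, ends, list members or genes; a named gene was called kept on its side of 2-fold. In a simulation, both columns were made from the BY4741 values with an assumed noise, which was not measured in arp5. Among genes of at least 10 FPKM, the 2-fold count found 47.5% of those given exactly 2-fold and 100% of those given 4-fold. Of unchanged lists, drawn at random over independent values, 94.5% lay inside the central 95%. That share follows from how they were drawn and says nothing about genes that change together. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.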

Results

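The series measured RNA by sequencing in budding yeast that lack the silencing factor Sir3 or subunits of the INO80 chromatin remodelling complex, and mapped Arp5 and a pair of histone H3 methylation marks on chromatin by immunoprecipitation and sequencing (ChIP-seq). Arp5 and Ies6 bind each other within the INO80 complex, Ies2 is a further subunit, and Ino80 is the ATPase. Of 27 libraries, 19 held RNA and 8 held ChIP DNA. RNA was read in the wild type BY4741, in its sir3, arp5, ies6 and ies2 deletion strains, all named as duplicates in the series text, in a sir3 arp5 double deletion with 1 library, and in the wild type CY337 and its ino80 deletion strain. The label BIOO was carried by 7 RNA libraries, 1 each of BY4741, arp5, ies6, sir3, the double deletion, CY337 and ino80. The ChIP libraries were 1 each of input, H3K79me3 and H3K4me3 in BY4741 and in arp5, and 1 each of input and Arp5 in strain CY1838. RNA values reached the deposited table as 1 FPKM column for each of the 8 genotypes over 6664 genes, so no value had a replicate, an SD or a test. The read depth is unknown, since no read totals come with the values. Median FPKM lay between 34.8 in the double mutant and 47.5 in ino80.

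The deleted genes lost their RNA in the strains named for them. SIR3 (YLR442C) went from 10.04 to 0.0572 FPKM in sir3 and was listed at 0 in the double mutant, while it stood at 12.9 in arp5 and 10.5 in ies6. ARP5 (YNL059C) had 35.02 FPKM in BY4741 and was listed at 0 in arp5 and in the double mutant. IES6 (YEL044W) went from 185 to 0.225 FPKM in ies6, and IES2 (YNL215W), with 62.8 in BY4741, was listed at 0 in ies2. INO80 (YGL150C) went from 22.1 to 0.523 FPKM in ino80 against CY337. LEU2, MET17 and URA3, which are auxotrophic markers deleted in BY4741, had 1279.6, 1124 and 94.6 FPKM in CY337 and 0.683, 0.119 and 0.228 in BY4741. HIS3, another marker, was at 165 in BY4741, 355 in arp5 and 3.22 in CY337.

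Cells without Sir3, the comparison that shows what silent chromatin keeps off, had little RNA of the a-specific genes, which encode the a-factor pheromone, its exporter and the receptor for the alpha-factor pheromone. The haploid-specific genes of the pheromone response, which the a1/alpha2 repressor turns off in diploids, fell with them. RNA from COS12 was higher, as was the median over genes near chromosome ends. MFA1 (YDR461W) fell from 50355 to 85.7 FPKM (log2 -9.18) and MFA2 (YNL145W) fell from 28717 to 133 (-7.75). AGA2 (YGL032C), an agglutinin subunit, fell from 1318 to 10.05 FPKM, the receptor gene STE2 (YFL026W) from 432 to 5.87, and BAR1 (YIL015W), which encodes a pheromone protease, from 134 to 4.15. All 7 a-specific genes fell, with a median log2 of -5.98. Of 12 haploid-specific genes, 11 fell (median -3.11), from FUS3 (YBL016W) with -5.01 and RME1 (YGR044C) with -3.76 to FAR1 (YJL157C) with -1.09; DIG2 stood at -0.087. The 4 alpha-specific genes had a median of 0.055. At the cassettes on chromosome III, HMLALPHA1 and HMLALPHA2 were listed at 0 in BY4741 and had 2.38 and 2.21 FPKM in sir3, HMRA1 went from 329.6 to 408 and HMRA2 from 197 to 381; the HMRA genes stayed below 2-fold, and the HML genes had too little RNA to be counted. BY4741 carries MATa, whose sequence HMR shares, so reads over the a genes cannot be placed at HMR with certainty.

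Among genes within 20 kb of an end, COS12 (YGL263W), a member of a subtelomeric family of membrane proteins, rose from 3.59 to 53.5 FPKM in sir3 (log2 3.57), and COS1 rose from 98.1 to 206. The COS genes had a median of 0.88, with 2 of 12 past 2-fold. YFR057W, a gene next to the right end of chromosome VI, was listed at 0 in BY4741 and at 29.6 FPKM in sir3. The PAU genes, seripauperins expressed under cold and low oxygen, had a median of 0.36 with 3 of 14 higher, among them PAU14 with 1.36. SNO2 and SNO3, paralogs in vitamin B6 metabolism, fell, from 22.3 to 5.99 and from 18.1 to 6.18 FPKM. The 288 genes of this zone had a median log2 of 0.30, where 95% of expression-matched random lists lay between -0.012 and 0.068, and 32 of 229 rose while 10 fell. The median was 0.35 at 0 to 5 kb, 0.52 at 5 to 10 kb, 0.19 at 10 to 20 kb, 0.13 at 20 to 30 kb and 0.029 at 30 to 50 kb. In the genome, 122 genes were more than 2-fold higher and 133 lower in sir3, 4.102% of 6216 counted; 72 were higher at a mean FPKM of at least 10 and 76 among genes of at least 300 bp. Stress genes had a median of 0.30; HSP12, a membrane chaperone, rose from 797 to 2484 FPKM and DDR2 fell from 998 to 234. ARG1, for arginine synthesis, rose from 36.9 to 101 FPKM. Amino acid synthesis had a median of 0.43, hexose transporters 0.36, glycolysis 0.26, sulfur and methionine genes 0.26 and the iron regulon 0.21. Flocculins had 0.35, inside the random range of -0.34 to 0.84. Phosphate genes (0.11), ribosomal proteins (0.083), ribosome biogenesis (-0.013), respiration (0.066), inositol and phospholipid synthesis (0.061), histones (-0.19), G1/S (-0.034), mitotic (-0.20), DNA damage (0.072), proteasome (-0.044), INO80 subunit (-0.15), silencing factor (-0.062) and strain marker genes (0.29) gave the other medians.

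Cells without Arp5 also had little RNA of a-specific genes and of the pheromone response. Their phosphate-starvation genes, which encode secreted phosphatases and phosphate transporters, were low. Genes for amino acid synthesis and of the iron regulon were high. MFA1 fell from 50355 to 1455 FPKM (log2 -5.11), MFA2 fell from 28717 to 949, STE2 from 432 to 13.5, BAR1 from 134 to 6.72 and AGA2 from 1318 to 93.9. All 7 a-specific genes fell (median -4.12), as did 9 of 12 haploid-specific genes (median -2.01), among them FUS3 with -3.67 and STE18 (YJR086W), the gamma subunit of the pheromone G protein, with -2.85. MF(ALPHA)1 (YPL187W), which encodes the alpha-factor pheromone, rose from 2.11 to 28.2 FPKM, and the 4 alpha-specific genes had a median of 0.89. At the cassettes, HMRA1 fell from 329.6 to 86.8 FPKM and HMRA2 from 197 to 94.5, and HMLALPHA1, listed at 0 in BY4741, had 3.49. HMR lies distal to MAT on III, where genes as a whole had a median of -0.72 in arp5. Diploid a/alpha cells could lower a-specific and haploid-specific RNA too, in arp5 as in ies6. The fall therefore cannot be assigned to a loss of silencing.

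In arp5, 10 of 17 phosphate genes fell and 1 rose (median -1.11). PHO89 (YBR296C), a sodium-coupled phosphate transporter, fell from 37.1 to 3.26 FPKM, and the acid phosphatase genes PHO12 (YHR215W) and PHO11 (YAR071W) fell from 164 to 22.04 and from 138 to 19.3. PHO84, the high-affinity transporter, went from 569 to 435 and PHO5 from 189 to 82.6 FPKM. Of 36 amino acid synthesis genes 16 rose (median 0.97), with ARG1 from 36.9 to 283 and ARG3 from 3.11 to 25.8 FPKM. Of 20 iron genes 5 rose (median 0.56), with the heme oxygenase gene HMX1 (YLR205C) from 10.5 to 91.3 and the cell wall gene FIT2 from 86.5 to 555. Sulfur and methionine genes had a median of 0.57, with 5 of 20 higher, MET28 first with 1.62. ZRT1 (YGL255W), the high-affinity zinc transporter, rose from 43.3 to 536 FPKM, and SNZ1 (YMR096W), for vitamin B6 synthesis, from 16.3 to 202. The stress genes split, with HSP12 up from 797 to 4909 and GRE1 at 2.94 while HSP42 fell from 291 to 52.4 and HSP78 stood at -1.95 (median -0.31). Ribosomal protein genes had a median of -0.43 against -0.28 in random lists of like expression, with 3 past 2-fold, RPL8A lowest with -1.63. Respiration genes (-0.36) held ACO1 at 1.39 and QCR10 at -1.22. Ribosome biogenesis had a median of 0.18, flocculins 0.61 (0.34 with a pseudocount of 5), hexose transporters 0.37, histones -0.45 and strain markers 0.29.

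Near the ends, the median RNA change in arp5 cells was a rise, while COS genes had a negative median and the acid phosphatase genes PHO11 and PHO12 fell. COS genes had a median of -0.76 with 5 of 11 lower, COS1 at -1.29. PAU genes had a median of 0.47, inside the random range of -0.054 to 0.59, with 4 of 14 higher, PAU4 at 1.92. THI5, for thiamine synthesis, rose from 1.67 to 8.14 FPKM, and DIA1 (YMR316W) fell from 137 to 21.3. The 282 genes within 20 kb had a median of 0.43 (random lists 0.054 to 0.20), with 34 higher and 20 lower of 229, and a median of 0.26 with a pseudocount of 5. With a pseudocount of 1 it was 0.43, 0.45 and 0.37 in the bins from 0, 5 and 10 kb and 0.20 from 20 to 30 kb. In the genome 408 genes were more than 2-fold higher and 252 lower, 10.4% of 6321, and 261 higher with a pseudocount of 5. The lists for glycolysis, inositol and phospholipid synthesis, INO80 subunits, silencing factors, proteasome, DNA damage, G1/S and mitotic genes had medians between -0.20 and 0.14.

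**Figure D1:**
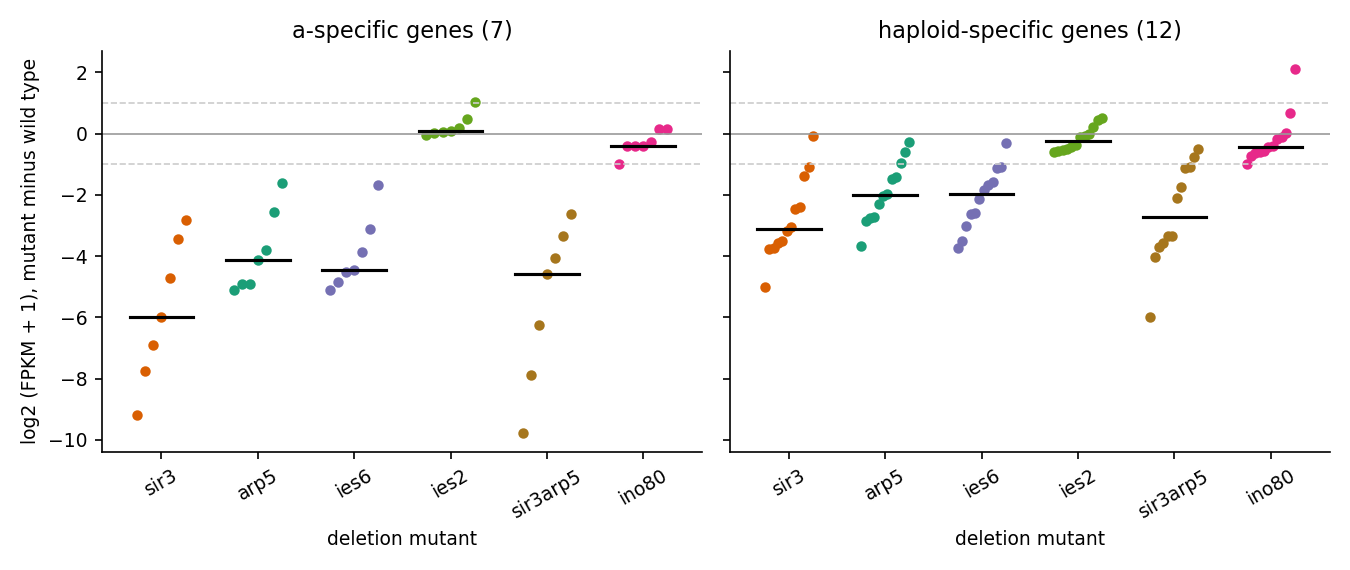
Log2 ratio of FPKM plus 1 in each mutant over its wild type (vertical axis) for 7 a-specific and 12 haploid-specific genes, each point a gene, bars the medians and dashed lines 2-fold. The a-specific medians are -5.98 in sir3, -4.12 in arp5 and -4.46 in ies6, against 0.086 in ies2 and -0.39 in ino80.

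Cells without Ies6 shared the loss of mating-type RNA and of phosphate-gene RNA with arp5, and added a rise of the environmental stress response. The stress genes, which encode small heat-shock proteins, catalase and enzymes of storage sugars, rose as a group. The hexose transporter genes HXT6 and HXT7 rose too. MFA1 fell from 50355 to 1472 FPKM and STE2 from 432 to 14.2. All 7 a-specific genes fell (median -4.46), and 11 of 12 haploid-specific genes did (median -1.99), among them NEJ1 (YLR265C), a regulator of DNA end joining, from 40.9 to 2.700. MF(ALPHA)1 rose from 2.11 to 69.7 FPKM, with a median of 0.56 for alpha-specific genes (random lists -0.43 to 0.61). HMLALPHA1, listed at 0 in BY4741, had 5.49 FPKM, and HMRA1 fell to 128, on the arm where genes as a whole had a median of -0.86. HSP12 rose from 797 to 21161 FPKM (log2 4.73), CTT1 (YGR088W), the cytosolic catalase, from 15.3 to 371, and 18 of 25 stress genes rose (median 1.64). CIN5 (YOR028C), a transcription factor of salt tolerance, rose from 12.7 to 263, and FMP45, a protein of the cell cortex, from 1.98 to 64.9. HXT6 and HXT7 rose from 207 to 973 and from 228 to 1032, and hexose transporters had a median of 0.60.

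Phosphate genes in ies6 had a median of -1.16, with 10 of 17 lower; PHO12 fell from 164 to 8.07 and PHO11 from 138 to 6.94 FPKM, and PHM7 stood at 3.24. Of 11 COS genes with at least 5 FPKM in either genotype 7 fell, COS10 lowest with -1.58. COS12, below that limit, stood at -1.77, and the median over 12 members was -1.17. HMX1 rose from 10.5 to 109 and FIT2 from 86.5 to 780.0 FPKM within an iron regulon median of 0.37. Amino acid synthesis had a median of 0.15, with 4 of 36 higher and ARG3 first with 2.04. Ribosomal protein genes had -0.51 against -0.36 in random lists, RPS22B lowest with -1.37. RNR4, a ribonucleotide reductase subunit, fell from 465 to 212 FPKM, with a median of -0.11 for DNA damage genes. Respiration (0.24), glycolysis (-0.31), flocculin (0.66) and PAU genes (0.029) gave further medians, and the lists for sulfur, histones, cell cycle, ribosome biogenesis, proteasome, inositol, INO80 subunits, silencing factors and markers lay between -0.19 and 0.13. Within 20 kb of an end MSC1 rose from 65.5 to 452 FPKM and PHO89 fell from 37.1 to 2.45. The median there was 0.067, at the low edge of the random range of 0.067 to 0.19, with 20 genes higher and 23 lower, from 0 to 5 kb it was -0.13, and within 10 kb -0.020. In the genome 360 genes were more than 2-fold higher and 228 lower, 9.35% of 6292.

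Cells without Ies2 kept the RNA of a-specific genes, and shared with ies6 the rise of stress genes and of HXT6 and HXT7. Their phosphate genes were low to a lesser degree. SPG1 (YGR236C) and SPG4 (YMR107W), which are needed for survival at high temperature in stationary phase, rose from 7.76 to 178 and from 15.8 to 224 FPKM. HSP12 rose from 797 to 10047 and GRE1 (YPL223C), a stress-induced hydrophilin, from 9.32 to 135; 14 of 25 stress genes rose and 2 fell (median 1.19), HSP42 at -1.82. BTN2 (YGR142W), which sorts misfolded proteins, fell from 221 to 18.9 FPKM, and CMK2 (YOL016C), a calmodulin-dependent kinase, from 349 to 63.9. HXT6 and HXT7 stood at 2.17 and 2.07 (list median 0.63, 4 higher). Phosphate genes had a median of -0.50, with 5 of 18 lower and 2 higher; PHO89 fell from 37.1 to 5.47 and PHO12 from 164 to 39.1 FPKM while PHM7 stood at 2.38. COS genes had -0.70, with COS8 down from 85.6 to 23.8, and the iron regulon 0.28, with HMX1 at 2.24. The a-specific median was 0.086, with MFA2 at 1.02; no haploid-specific gene passed 2-fold, with a median of -0.25 just below the random range of -0.23 to 0.22, and alpha-specific genes had 0.43. Amino acid synthesis had 0.18 with ARG3 at 1.83, ribosomal proteins -0.43 against -0.33 in random lists, flocculins 0.63 (0.29 with a pseudocount of 5) and PAU genes 0.35. The other lists lay between -0.33 and 0.24. Within 20 kb of an end MSC1 rose from 65.5 to 241 FPKM and DIA1 fell from 137 to 27.01; the median was 0.30 (random lists 0.091 to 0.20), with 18 higher and 11 lower, and 0.19 with a pseudocount of 5. In the genome 244 genes were more than 2-fold higher and 117 lower, 5.75% of 6273, and 160 higher with a pseudocount of 5.

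The sir3 arp5 double mutant, which sets loss of Arp5 beside loss of Sir3 in a single strain, had little RNA of a-specific genes. It had low phosphate and stress RNA and high RNA near the chromosome ends. Sulfur and methionine genes and genes for amino acid synthesis were high. MFA1 fell from 50355 to 56.04 FPKM and STE18 from 514 to 7.03; 7 of 7 a-specific genes fell (median -4.58), and 10 of 12 haploid-specific genes (median -2.72). CYS3 (YAL012W), of cysteine synthesis, rose from 251 to 1283 (sulfur and methionine median 1.02, 10 of 20 higher), and ILV6 (YCL009C), of isoleucine and valine synthesis, from 201 to 1557 (amino acid median 0.89). FTR1, the iron permease, rose from 163 to 984 (iron median 0.58). Of 18 phosphate genes 13 fell (median -1.597), SPL2 (YHR136C) from 303 to 30.1 FPKM, and of 25 stress genes 14 fell and 3 rose (median -1.15), HSP42 at -3.24 and GRE1 at 3.17. The glucose transporter gene HXT4 fell from 155 to 11.1 (hexose median 0.97), and QCR8, of the respiratory chain, from 1622 to 326 (respiration median -0.45, 10 lower). Ribosomal proteins (0.40, random lists 0.43), flocculins (1.23, or 0.76 with a pseudocount of 5), PAU (0.76), COS (-0.26), glycolysis (0.35), cassette (-0.098) and alpha-specific genes (0.54) gave further medians; the others lay between -0.46 and 0.37. In the genome 1061 genes were more than 2-fold higher and 659 lower, 27.1% of 6343. The double mutant had a single library, labelled BIOO, so what belongs to the genotype and what to the library cannot be told apart. Genes under 150 bp held 65.9% of all its FPKM, against 45.7% in BY4741.

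Near the ends, the double mutant had COS12 at 40.7 FPKM and THI5 at 23.9, against 3.59 and 1.67 in BY4741, and YFR057W at 10.4. The 299 genes within 20 kb had a median of 0.97 over BY4741 (0.62 with a pseudocount of 5), with 125 of 261 higher and 23 lower, and medians of 1.103, 1.17, 0.61 and 0.19 in the bins from 0, 5, 10 and 20 kb. Against sir3, the vitamin B6 genes SNZ3 and SNZ2 rose from 7.71 to 65.3 and from 8.63 to 60.7 FPKM, the purine gene ADE17 (YMR120C) fell from 835 to 24.7 and HSP30 (YCR021C) from 892 to 29.99; the zone had a median of 0.48 (80 higher, 34 lower), COS genes -1.03, phosphate genes -1.84 and stress genes -1.601. Against arp5, COS12 rose from 2.02 to 40.7 FPKM, IMD2 (YHR216W), an IMP dehydrogenase, from 29.9 to 231, and MFA1 fell from 1455 to 56.04; the zone had 0.46 (64 higher, 12 lower), COS genes 0.62, a-specific genes -0.999, phosphate genes -0.41 and stress genes -1.05. Past 2-fold were 874 genes higher and 550 lower against sir3, and 778 and 417 against arp5, where 264 were lower without I, III, XI and XII. The zone against arp5 had 0.30 with a pseudocount of 5 and 0.30 at 30 kb.

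**Figure D2:**
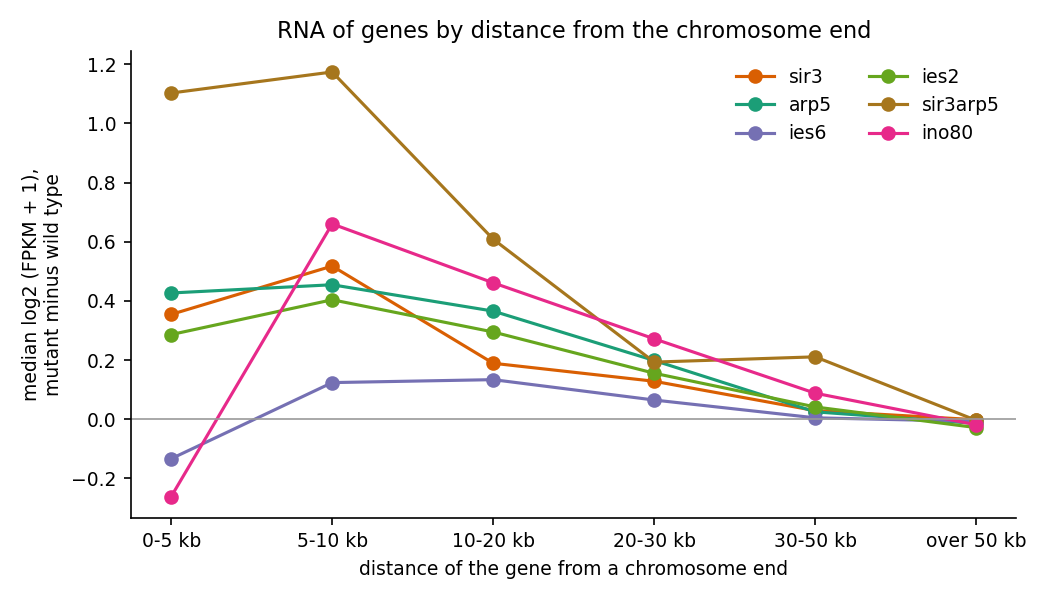
Median log2 ratio of FPKM plus 1 (vertical axis) of genes binned by distance from a chromosome end in kb (horizontal axis), a line for each mutant over its wild type. From 0 to 5 kb the medians are 1.103 in the double mutant, 0.43 in arp5, 0.35 in sir3, -0.13 in ies6 and -0.26 in ino80.

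Cells without the ATPase Ino80, compared with CY337, had the lowest phosphate-gene median of the single mutants. By their names the CY337 and ino80 columns are read as 1 library each. Genes of glycolysis were low, and the PAU and iron genes high. The a-specific genes kept most of their RNA. PHO84 (YML123C) fell from 813 to 27.3 FPKM (log2 -4.85), PHO12 from 117 to 4.65, PHO11 from 101 to 6.24 and SPL2 from 210.3 to 17.1; 14 of 18 phosphate genes fell, while GIT1 and PHM7 rose (median -1.82). Of 16 glycolysis genes 9 fell (median -1.13), ENO1 from 4534 to 1485 FPKM. The fatty acid synthase genes FAS1 and FAS2 stood at -1.401 and -1.16 within a median of -0.53 for inositol and phospholipid synthesis; INO1, the inositol synthase after whose regulation the complex is named, went from 5.59 to 11.4 FPKM. CMK2 fell from 659 to 50.2 and DIA1 from 359 to 36.2 FPKM. HSP12 rose from 685 to 13399.9 with a stress median of 0.22, FIT2 from 54.01 to 574 with an iron median of 0.55, and 10 of 17 PAU genes rose (median 1.08). Sulfur and methionine genes had -0.50, with MET16 at -1.61, histones -0.63, with HTA1 at -1.27, and DNA damage genes -0.057, with RNR2 at -1.45. MF(ALPHA)1 rose from 0.718 to 28.2 FPKM and the alpha-specific median was 0.93. MFA2 stood at -1.002 within an a-specific median of -0.39, and FUS1, for cell fusion, rose from 13.1 to 59.9 within a haploid-specific median of -0.43. FUS1 and GIT1 lie on chromosome III, where genes as a whole had a median of 1.01 in ino80 relative to chromosomes without a shift. Ribosomal proteins had -0.42 against -0.41 in random lists, and COS genes -0.11; the other lists lay between -0.29 and 0.63. Within 20 kb of an end the median was 0.35 (random lists 0.12 to 0.29), with 61 higher and 29 lower, and from 0 to 5 kb -0.26. In the genome 529 genes were more than 2-fold higher and 328 lower, 13.4% of 6406.

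Arp5 and Ies6, which work as a pair in the complex, gave more alike RNA changes than the other pairs set against BY4741. The medians of a-specific, phosphate and COS genes were negative in both, and HMX1, FIT2 and ARG3 went up in both. The stress genes set them apart. Across 6606 genes, which are not independent replicates, the log2 ratios of arp5 and ies6 had a Pearson r of 0.695 and a Spearman rho of 0.6497, and a covariance of 0.414. They share the BY4741 column, which alone gave a simulated r of 0.499 and a covariance of 0.243 at most. The simulation gave every column the same spread at each expression level, taken from the difference between ies2 and sir3. An r of about 0.499 was thus fixed by its setting for every pair. The r was 0.564 for arp5 and ies2 and 0.643 for ies6 and ies2. It was 0.488 for arp5 and sir3, 0.498 for ies6 and sir3, and 0.3796 for ies2 and sir3. The last 3 do not exceed the simulated value, which does not show that these pairs share only the control. Lower in both were 44 genes in arp5 and sir3 (5.43 by chance), 67 in ies6 and sir3 (4.92) and 19 in ies2 and sir3 (2.53). That chance leaves out the shared control. Against ino80, which shares no control, r was 0.337 for arp5, 0.312 for ies6 and 0.322 for ies2, with covariances of 0.238, 0.219 and 0.191; these hold no share from a common control and are not ranked against the pairs above. There were 169 genes higher in arp5 and ino80 (27.5 by chance) and 86 lower (11.8 by chance). In this family 9 correlations were computed.

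Whole parts of chromosomes shifted in some mutants. On chromosome III, the arm distal to the mating-type locus MAT, which holds essential genes such as TAF2, RSC6 and CDC39, had low RNA in arp5 and ies6 and not in ies2 or sir3. In ino80 the whole of chromosome III was high, and in arp5 chromosomes XI and XII were. Relative to chromosomes without a shift, the median log2 of genes distal to MAT was -0.72 in arp5 and -0.86 in ies6, with 97.8% of 45 genes below the rest in each, against 0.086 in ies2, 0.090 in sir3 and 0.95 in the double mutant. Genes from the left end of III up to MAT had 0.033 in arp5 and 0.077 in ies6. All of III had 1.01 in ino80, and in arp5 XI had 0.44 and XII 0.47. Chromosome I had 0.43 in the double mutant, with quartiles of -0.21 and 1.13 over 88 genes. TAF2 (III 201174 to 205397) went from 12.1 FPKM in BY4741 to 6.01 in arp5 and 6.23 in ies6, and CDC39 from 12.04 to 6.64 and 7.296; these genes were chosen after their values were seen. In the authors' deposited table of arp5 over BY4741 H3K79me3, windows distal to MAT stood at -1.08 relative to chromosomes without a shift, while the difference of the ratios over input was -0.084. In the same deposited table XI stood at 0.20 and XII at 0.12, and the differences of the ratios over input there were -0.038 and 0.019.

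**Figure D3:**
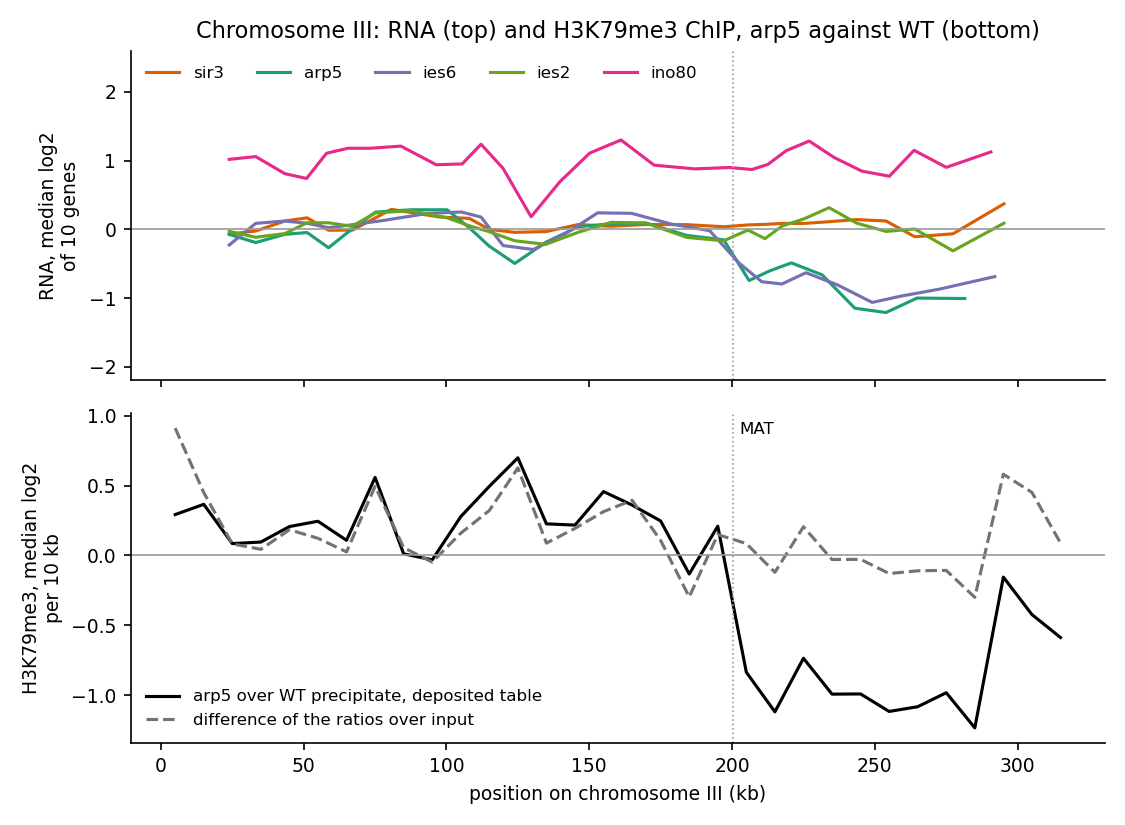
Position on chromosome III in kb (horizontal axis) against the median log2 RNA ratio of 10 neighbouring genes for sir3, arp5, ies6, ies2 and ino80 (upper panel) and against the arp5 over BY4741 log2 of H3K79me3 in 10 kb steps, from the authors' deposited table and from the ratios over input (lower panel); the dotted line is MAT. Beyond MAT the RNA lies at -0.72 in arp5 and the deposited table at -1.08 relative to chromosomes without a shift.

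Arp5 itself, mapped in strain CY1838 after a nocodazole arrest and release into alpha-factor, lay at promoters more than along genes. Promoters of a-specific, glycolytic, phosphate and ribosomal protein genes were mostly covered by it, and those of COS and PAU genes mostly were not. The windows and their log2 over input are the authors' list of significant windows. That list held 84757 windows of 50 bp, 35.1% of the nuclear genome, in 8198 runs with a median length of 300 bp. Promoters, taken as 500 bp before the gene, held 45.1% of them against 25.4% of all windows, a ratio of 1.77, and gene bodies 49.7% against 75.9% (0.655, or 0.272 for windows of log2 at least 1). Among promoters with the highest mean log2 were those of KAR5 (YMR065W), for nuclear fusion in mating, with 1.89, and of PDC1 (YLR044C), the pyruvate decarboxylase, with 1.88. GAT1 had 1.88 and PHO13 1.78, and further down came AGA2 with 1.63 and BAR1 with 1.56. These genes were chosen after the values were seen. Whether the release into alpha-factor raised the signal at mating genes was not tested, and the cells for RNA grew in YPD. At least 50% of the promoter was listed for 67.1% of all genes, 7 of 7 a-specific, 11 of 12 haploid-specific, 16 of 16 glycolysis, 17 of 18 phosphate, 35 of 36 amino acid, 23 of 25 stress and 128 of 138 ribosomal protein genes, and for 3 of 12 COS and 9 of 24 PAU genes. Of genes past 2-fold in arp5, 73.8% of the higher and 69.2% of the lower (ARP5 included) had such promoters, near the share of all genes. So had 4 of 4 alpha-specific genes and 7 of 7 strain markers. Within 20 kb of an end lay 4.37% of the windows against 5.31% of the genome (ratio 0.824). From 0 to 5 kb 12.7% of windows were listed, and beyond 50 kb 35.6%.

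Trimethylation of H3 at lysine 79 and at lysine 4, which mark euchromatin and are low in silent chromatin, were compared between BY4741 and arp5 to see whether they enter silent regions without Arp5. Both were low near chromosome ends in BY4741, H3K79me3 also over HML and HMR and H3K4me3 over HML. In arp5 the H3K79me3 ratio over input was higher near most ends, while H3K4me3 moved little there. The median H3K4me3 window difference was -0.00071 within 20 kb and -0.082 beyond 50 kb. In the bins from 0 and 5 kb it was -0.076 and -0.074, much as in the interior. In BY4741, 12.5% of windows within 20 kb of an end were on the authors' list of significant H3K79me3 windows against 36.1% beyond 50 kb, and 7.93% against 29.6% for H3K4me3. The median H3K79me3 log2 within 20 kb was -1.23 in BY4741 and -0.78 in arp5. The median over windows of the arp5 minus BY4741 difference was above 0 at 32 of 32 ends, although the arp5 median itself was below that of BY4741 at the left ends of II, XII and XIII and the right end of VII. Over the ends this difference had a median of 0.33, where random sets of interior stretches gave -0.034 to 0.091; within 10 kb it was 0.20. The median of the window differences was 0.093 from 0 to 5 kb, 0.52 from 5 to 10 kb and 0.37 from 10 to 20 kb; from 0 to 5 kb the medians themselves went the other way, from -0.53 in BY4741 to -0.60 in arp5. All arp5 H3K79me3 ratios spanned a narrower range than those of BY4741, with an SD over windows of 0.8502 against 1.24. Against interior windows of the same BY4741 level, a measure added after the values were seen, the median excess within 20 kb was -0.045 and 6 of 32 ends had an excess above 0. For H3K4me3 the medians were -2.696 and -2.59, with a median of window differences above 0 at 14 of 32 ends, at 7 within 10 kb and at 29 once each table was centred on its genome median. Without centring the median over the ends was -0.022, above the -0.13 to -0.043 of random sets of interior stretches, while the median excess over interior windows of the same BY4741 level was -0.11 within 20 kb.

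At HML (III 12386 to 13809) H3K79me3 went from -1.59 in BY4741 to -1.17 in arp5 and H3K4me3 from -1.49 to -0.60. At HMR (III 293179 to 294321) H3K79me3 went from -1.43 to -1.09 and H3K4me3 from 0.39 to -0.098. At MAT (III 199546 to 200969), which shares sequence with both, H3K79me3 went from -1.84 to -0.92 and H3K4me3 from -1.57 to -0.39. In sequence beyond HML (III 14351 to 15300) that MAT does not share, H3K4me3 went from -5.77 to -2.62, and in sequence before HMR (III 291701 to 292650) from -3.99 to -4.03. At YFR057W on VI H3K79me3 went from -1.86 to -1.23. Across genes, the arp5 change in H3K79me3 over the gene and the change in RNA had a Pearson r of 0.2102 and a rho of 0.146 over 6560 genes (r 0.0959 with the excess over matched interior windows), and 0.146 and 0.253 over the 282 within 20 kb of an end; genes are not independent replicates.

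**Figure D4:**
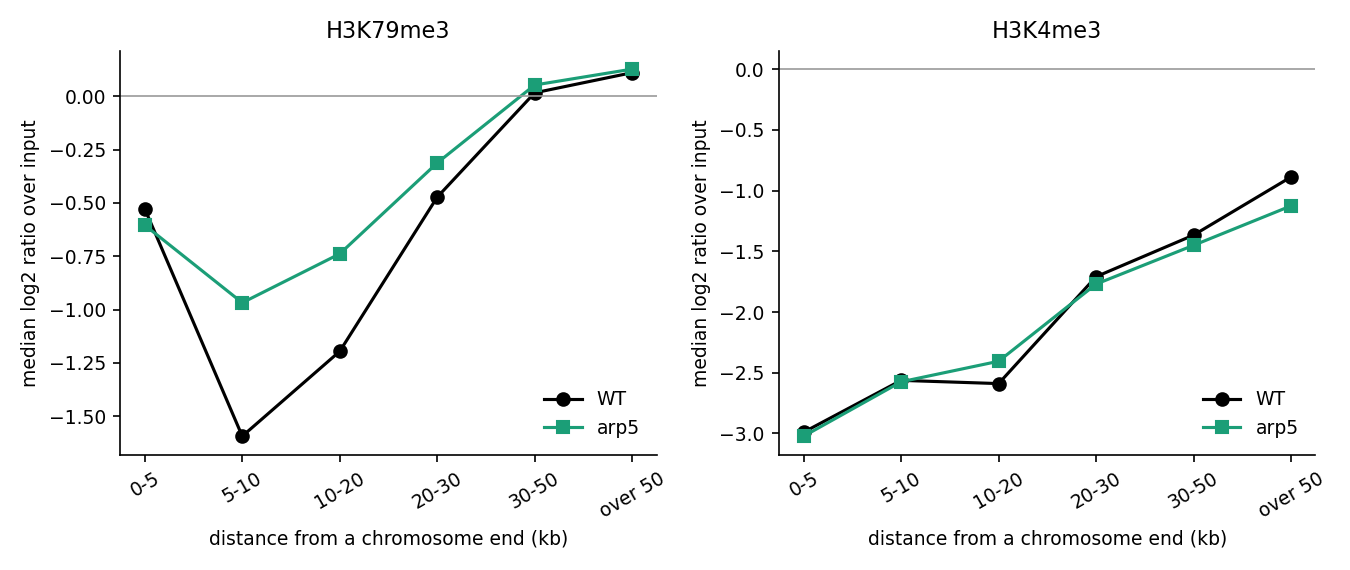
Median log2 ratio over input of H3K79me3 and H3K4me3 (vertical axes) in windows binned by distance from a chromosome end in kb (horizontal axis), with lines for BY4741 and arp5. From 5 to 10 kb H3K79me3 is at -1.59 in BY4741 and -0.97 in arp5, and H3K4me3 at -2.56 and -2.57.

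By the authors' deposited values for each strand, RNA antisense to genes was higher in arp5, ies6 and ino80, and sense RNA was too, to a lesser degree. In these mutants the rise was larger before and behind genes than along them, on the sense strand as well as the antisense strand. RAP1, which encodes an essential regulator of telomeres and ribosomal protein genes, carried high antisense RNA in arp5, ies6 and ino80, and PHO84 did in ino80. In sir3 the mean stayed near 0, with single genes such as BAR1 high. In the authors' deposited tables by strand, over 1556 genes, the mean log2 of antisense RNA along the gene was 0.47 in arp5, 0.30 in ies6, 0.020 in sir3 and 0.83 in ino80, with 322, 221, 89 and 594 genes at least 2-fold higher and 36, 55, 58 and 15 at least 2-fold lower. Downstream of the gene in the authors' deposited tables it was 0.82, 0.65, 0.14 and 1.18. Sense RNA in these tables had means along the gene of 0.27, 0.18, -0.064 and 0.58, in the same order of mutants. On this strand 165, 131, 31 and 372 genes were at least 2-fold higher and 47, 68, 70 and 34 at least 2-fold lower. Before the gene the sense means were 0.51, 0.41, 0.034 and 0.86, and downstream of it 0.42, 0.30, 0.036 and 0.81. By FPKM the median log2 over counted genes was -0.0034 in arp5, -0.012 in ies6, 0.0035 in sir3 and -0.010 in ino80 against CY337. A shift common to both strands was not tested for, so how much of the antisense rise belongs to that strand alone is open. Antisense to RAP1 the authors' deposited tables gave 3.94 in arp5, 3.47 in ies6 and 3.96 in ino80. PHO84 in ino80 had 4.58 antisense and -3.82 sense, and BAR1 in sir3 2.54 antisense and -6.29 sense; these genes were chosen after their values were seen. The authors' deposited tables for both strands, over 6691 genes, had means of 0.11 in arp5, 0.13 in ies6, 0.12 in ies2 (median 0.064), -0.079 in sir3 and 0.26 in ino80. The ino80 tables by strand are named against BY4741, yet their sense values follow the ratio to the CY337 column (r across genes 0.568) more than that to BY4741 (0.446), so their control is uncertain. The kit named for the RNA libraries does not keep the strand of the RNA. Tables by strand exist for sir3, arp5, ies6 and ino80, which have a BIOO library. They do not exist for ies2, which has no such library, or for the double mutant, which does. Which libraries gave the tables and how the strands were told apart is not given in the sources used here. What the values by strand measure is therefore uncertain.

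**Figure D5:**
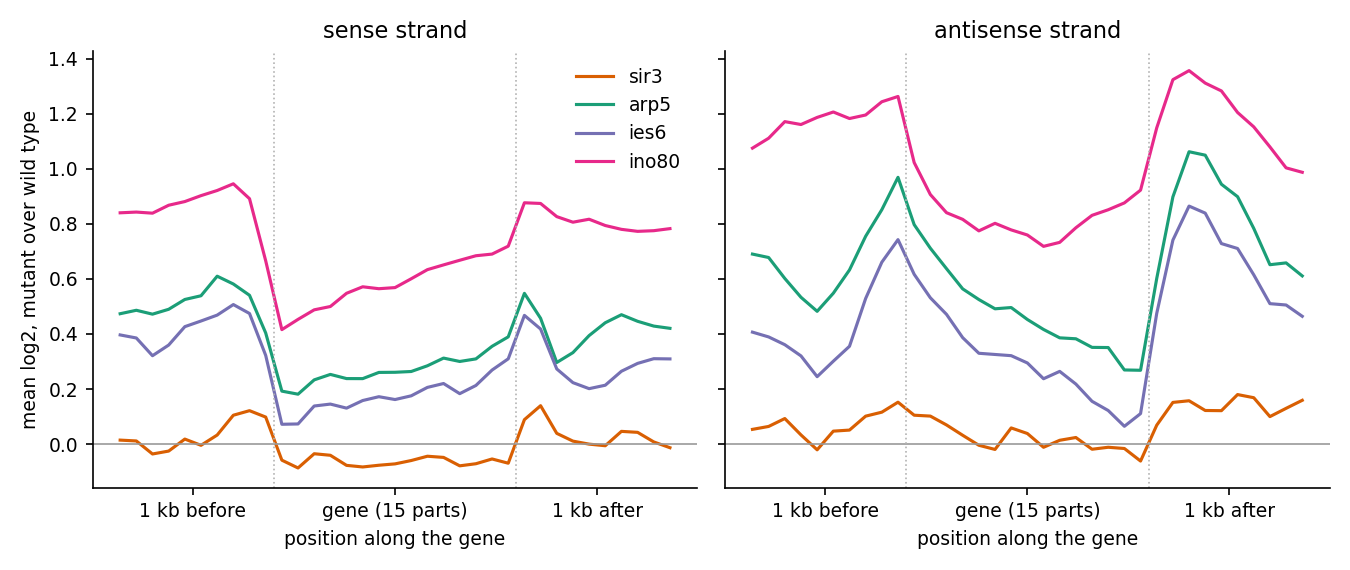
Mean log2 ratio of mutant over wild type (vertical axis) over 1556 genes in windows before, along and after the gene (horizontal axis), sense and antisense, from the authors' deposited tables for sir3, arp5, ies6 and ino80. Downstream of the gene the antisense means are 1.18 in ino80 and 0.14 in sir3.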

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

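The tests of mitochondrial DNA, of the narrower range, of the chromosome ends and of background were chosen only after the H3K79me3 values were seen.

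Mitochondrial windows, which the comparisons of the report do not use and which carry no histones, held a signal that differed between the libraries. Their median H3K79me3 log2 over input went from -5.28 in BY4741 to -3.305 in arp5, a median difference of 1.996 over 1716 windows. For H3K4me3 the difference was -0.080.

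The higher H3K79me3 ratio near chromosome ends in arp5 was weighed beside this. Of 32 ends, 6 exceeded interior windows of the same BY4741 level, so no common gain beyond such windows was seen. The match rests on the BY4741 values of 1 library. Their noise can lower the excess where levels are low, so a gain particular to the ends is not excluded. A narrower range of all arp5 ratios, ends and interior alike, may account for the higher ratio near the ends. The median excess within 20 kb was -0.045, with the same limit. More unspecific DNA in the arp5 precipitate is a candidate source of at least part of that narrowing, from the mitochondrial gain of 1.996. A background of 7.75%, as this gain gives, brings the BY4741 median to -1.08 and leaves arp5 higher by 0.30. That size takes unspecific nuclear DNA to be carried over at the mitochondrial rate, which was not measured. Background as the whole cause is therefore not excluded. A change of H3K79me3 across the whole genome in cells without Arp5 stays open and untested, as there is 1 library per genotype.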

How the results depend on the processing

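The alternatives on gene length, genes listed at 0, shifted chromosomes, matched interior windows and the sense table were chosen after seeing the data. No paired analysis was possible because the RNA table has 1 column per genotype; for that reason the replicate block, leaving out a replicate, limma and camera tests, an added fold minimum, the spread of only 4 libraries and other choices of libraries were not run, for RNA against H3K79me3 included. Unknown depth limits genes near 0. The a-specific, haploid-specific and phosphate medians of sir3, arp5 and ies6 kept their direction under the pseudocount and scaling alternatives. Counts past 2-fold ranged over 169 to 312 genes in sir3, 469 to 733 in arp5, 439 to 668 in ies6, 251 to 421 in ies2, 1339 to 1820 in the double mutant and 656 to 915 in ino80. Counts that moved by more than 1.5 times were those of sir3, with 169 past 2-fold and 72 higher at a mean FPKM of at least 10, where fewer genes were counted, and 76 higher among genes of at least 300 bp; 261 higher in arp5 and 160 in ies2 at pseudocount 5; and 264 lower in the double mutant against arp5 without I, III, XI and XII. Of named gene values, 70 dropped below 2-fold at pseudocount 5, 20 passed it at 0.1, and centring moved 2 past and 1 below it. Of list medians, 609 stayed and 9 moved without a change of sign, mostly those of flocculins; those of mitotic genes in arp5, ribosome biogenesis in sir3 and silencing factors in ino80 lay on either side of 0.

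For the following the cause was not tested. Medians within 20 kb became, at pseudocount 5, 0.21 in sir3, 0.26 in arp5, 0.19 in ies2, 0.62 in the double mutant and 0.30 for it against arp5; at 10 kb, 0.40 in sir3, 1.11 in the double mutant, 0.67 against sir3, 0.66 against arp5 and, with a changed sign, -0.020 in ies6; at 30 kb, 0.22 in sir3, 0.67 in the double mutant and 0.30 against arp5. Arp5 windows of log2 at least 1 gave ratios of 2.21 for promoters, 0.272 for gene bodies and 0.6797 within 20 kb. The H3K79me3 difference over the ends was 0.20 at 10 kb, 0.25 at 30 kb and, with a changed sign, -0.043 against matched interior windows, where 6 ends were higher. H3K4me3 centred on the genome median gave 0.20 and 29 higher ends, and at 10 kb 7. Medians over genes in the authors' deposited tables were, antisense, 0.38 in arp5, 0.21 in ies6, 0 in sir3 and 0.70 in ino80; sense, 0.12 in ies6 and 0 in sir3; both strands, 0.086 in ies6, 0.064 in ies2 and 0.22 in ino80. Genes of at least 5 FPKM gave 0.52 for sense in ino80 and, for both strands, 0.085 in ies6, 0.081 in ies2, -0.097 in sir3 and 0.24 in ino80. With genes of at least 300 bp r was 0.427 for ies6 and sir3 and, against ino80, 0.456 for arp5, 0.428 for ies6 and 0.428 for ies2. The r of H3K79me3 and RNA changes was 0.0959 with the matched excess and 0.163 with the sense table.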

Other observations

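The test of the combined RNA patterns in the sense tables and the test of diploid cells were set before their results were seen, and the tests of H3K79me3 on chromosome III, of SIR3 RNA and of H3K4me3 beyond HML were chosen only after.

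Genes of the alpha cell type were read in strains built from a MATa wild type. MATALPHA1, the activator of alpha-specific genes, had 0.208 FPKM in BY4741, 4.32 in sir3, 7.14 in arp5 and 7.74 in ies6. It had 6.31 in the double mutant and 2.95 in ino80, and was listed at 0 in CY337. HMLALPHA1, listed at 0 in BY4741, CY337 and ino80, had 2.38 in sir3, 3.49 in arp5, 5.49 in ies6 and 2.77 in the double mutant. MAT and HML share sequence, so reads over these genes cannot be placed at either with certainty. IMD2, next to the right end of VIII, went from 49.6 to 169 FPKM in sir3 and to 231 in the double mutant. TAR1, a gene antisense to the ribosomal DNA, went from 492 to 7812 in the column of the double mutant, where YLR154W-A and YLR154W-B beside it went from 1172 to 26426 and from 1633 to 38039; that column holds a single library, labelled BIOO, with 65.9% of its FPKM in genes under 150 bp, so these values cannot be assigned to the genotype.

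Genes distal to MAT on chromosome III were lower in arp5 and ies6, those on XI and XII higher in arp5 and those on III higher in ino80. Against the preparation or scaling of RNA libraries as the source for arp5 on III speaks the authors' deposited table of arp5 over BY4741 H3K79me3, at -1.08 there, where 93 stretches of other chromosomes ranged from -0.16 to 0.23; a change of transcription or of the mark with no change of DNA is argued against by the ratios over input, which differed by -0.084. A change in DNA copy number distal to MAT may therefore lie behind the arp5 values, since the table without input shows -1.08 and the ratios over input do not. For the patterns as a set, library preparation and other sources cannot be told apart: the sense tables gave -0.32 in arp5, -0.45 in ies6 and 0.73 in ino80, and hold only 13 genes distal to MAT. The double mutant, at 0.95 there, did not share the loss, and ies6 and ino80 had no ChIP to test.

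The a-specific and haploid-specific genes were lower in arp5 and ies6, as in sir3. An admixture of sir3 cells or a swap with sir3 libraries is argued against by SIR3 RNA, which stood at 1.04 times its BY4741 value in the lower of arp5 and ies6. Diploid a/alpha cells could give the pattern and stay open in arp5. Genes on XI and XII stood at 0.34 in the sense table, and by FPKM at 0.44 on XI and 0.47 on XII. The authors' deposited table of arp5 over BY4741 H3K79me3 stood at 0.20 on XI and 0.12 on XII. The ratios over input differed there by -0.038 and 0.019. Whether XI and XII had extra copies stays open, and diploid cells need none, so these values do not decide. On III distal to MAT that deposited table stood at -1.08. The arm holds essential genes such as TAF2, which had 6.01 FPKM in arp5 against 12.1 in BY4741. These values bear on the copies of III, since haploid cells cannot lose their only copy of an essential gene. A lower dose of the arm would therefore point to cells with more than 1 copy of the rest of III. The test of diploid cells did not use these values, and they do not show whether such cells were a/alpha. Loss of silencing at HML could give the lower a-specific and haploid-specific RNA too. H3K4me3 beyond HML exceeded matched interior windows by 0.92 in arp5. Of 4033 overlapping interior stretches with low BY4741 H3K4me3, 150 had as much, which puts this excess at percentile 96.3. Most of the weighing thus rests on 1 short stretch in 1 library, which does not decide. The explanations therefore cannot be told apart. A change in the MAT locus itself was not tested apart from these, and ies6 had no ChIP.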
